A study of Mus musculus with 6 samples.

How the data were processed

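ILC1s and NK cells were sorted from MC38 tumours 14 days after subcutaneous transplantation, directly into TRIzol, and 3 samples of each cell type were sequenced. Per the labels' protocols, mRNA was selected with oligo(dT) beads, cDNA was primed with random hexamers, and single-end reads of 50 bases were made on a BGISEQ-500 instrument. The authors deposited a table of raw counts with 55291 gene symbols and a column for each of the 6 samples. HISAT2 2.1.0 and featureCounts 2.0.1 with the GRCm38 build are named, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene, or of near-identical copies such as the Gzm and Klra clusters, may therefore be shared or lost. Selection by poly(A) tails leaves out most transcripts without them. No unique molecular identifiers are described, so counts include PCR copies.

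Groups were taken from the cell type label and columns were matched to samples by name. The counts per library ran from 16931099 to 20224847, at which 3 counts, the limit that a count of 0 allows, equal 0.144 to 0.174 CPM, for counting error only. At 29106 symbols all 6 libraries held 0. Every row carried a gene symbol, and 53292 of the symbols were found in GENCODE M21 on GRCm38. Positions are 1-based and come from that annotation, except that of Trgc4, which was matched by symbol in RefSeq on the same build.

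Values in CPM were computed from the deposited counts with TMM-scaled library sizes, and means are given ± SD over 3 libraries. The comparison used edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr (14475 genes tested), robust quasi-likelihood fits with cell type as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are ILC1 minus NK, and their SE comes from the same fit. With 3 against 3 libraries, an exact permutation test of a single gene cannot give a two-sided p below 0.1, so single genes were judged by the model fitted across genes. The groups did not overlap in CPM for 3741 genes (25.8%, where 10% is given by chance), and 2283 genes had an unadjusted p under 0.05, where chance gives 724. The common dispersion was 0.352.

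Before the data were examined, 29 gene lists were fixed, 10 of them markers of other cell types that a sort gate could hold, and each was tested as a set with camera in limma 3.58.1. Camera was run with a preset correlation of 0.01 on lists with at least 5 tested members, adjusted over the 29 lists, and again with the correlation estimated from the data. Each list was also adjusted over its own members alone. The rule for named genes was fixed at the same time. It names 8 lineage and gate genes whatever their result, the 8 genes with the largest and the 8 with the smallest fold change among those past the test with at least 10 CPM in the higher group and no overlap (leaving out unnamed gene models and receptor segments), up to 4 members of each list with the smallest p, and up to 3 members of each marker list with the highest level. Genes outside the rule are said to have been named after their values were seen, and some genes that the rule names are not reported here.

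Pairs of libraries were compared by Pearson correlation of log2 CPM with a prior count of 2, and by a chi-square test of their counts over genes with at least 20 counts, to look for libraries deposited more than once. None was found. The labels number the replicates 1 to 3 in both cell types without saying that a number marks a shared mouse or day.

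The alternatives fixed before the data were examined were RLE and upper-quartile normalization, no low-count filter, a minimum mean of 5 CPM, a replicate block, each library left out in turn, DESeq2 1.42.0, limma-voom, an estimated correlation for the lists, a prior count of 0.5, and the 500 most variable genes for sample similarity. Alternatives for values that are not counts did not apply. After the libraries were seen to differ in matrix and macrophage genes, 3 alternatives were added. These were a term for library sets (NK replicates 1 and 2, NK replicate 3 with ILC1 replicates 1 and 2, and ILC1 replicate 3), limma-voom with estimated library weights, and NK replicate 3 with ILC1 replicates 1 and 2 alone. Levels within the matrix-rich libraries compare the mean of ILC1 replicates 1 and 2 with NK replicate 3, with 0.1 CPM added to each.

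The test was tried on simulated counts for the same 14475 genes with 200 genes changed. With the spread of the real libraries, 1 of 50 genes changed 2-fold was recovered, 29 of 50 changed 4-fold, 41 of 50 changed 8-fold and 45 of 50 changed 16-fold, with 8 unchanged genes called. With the dispersion capped at 0.05, 30, 50, 50 and 50 were recovered with 2 unchanged genes called. Camera recovered the cell proliferation list, raised 2-fold, in 20 of 20 draws. It called 2 of 560 tests of other lists. Genes were drawn independently, whereas estimated correlations in the real lists reached 0.881, so this rate does not carry over to them. All 6 samples were used.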

Results

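RNA was sequenced from type 1 innate lymphoid cells (ILC1s) and natural killer (NK) cells that had been sorted from subcutaneous MC38 tumours of wild-type C57BL/6 mice 14 days after transplantation. MC38 is a mouse colon carcinoma cell line of C57BL/6 origin. ILC1s and NK cells are the members of group 1 innate lymphoid cells, which share T-bet (Tbx21) and the receptors NKp46 (Ncr1) and NK1.1 (Klrb1c). ILC1s are mostly tissue resident and NK cells circulate. Each cell type had 3 libraries. The NK libraries held 19814075, 19743878 and 19551574 counts for replicates 1 to 3, and the ILC1 libraries held 16931099, 19879100 and 20224847. Counts above 0 were found for 15819, 15862 and 20772 genes in the NK libraries and for 21799, 21872 and 19402 genes in the ILC1 libraries. The surface markers of the sort are not given in the sources used here. Nor do the labels say whether the 3 samples of a cell type came from separate mice, so p-values measure only the spread between these samples.

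The single comparison asked how the transcriptomes of ILC1s and NK cells in the same tumour model differ. ILC1s had far more mRNA of the granzymes C, E and G, of the inhibitory receptor PD-1 (Pdcd1) and of the chemokine receptor Cxcr6. Gzmc reached 5821 ± 1443 CPM in ILC1s and 388 ± 22.2 CPM in NK cells (mean ± SD, n = 3 each), a 15.01-fold difference. Pdcd1 reached 122 ± 59.2 CPM against 4.07 ± 0.359 CPM, a 29.8-fold difference, and Cxcr6 reached 72.4 ± 16.98 CPM against 5.55 ± 1.87 CPM. Trdc, the constant region of the T cell receptor delta chain, was the gene that fell, with 29.1 ± 3.07 CPM in ILC1s and 103 ± 14.2 CPM in NK cells. Of 14475 genes tested with edgeR's quasi-likelihood test, 11 were higher and 1 was lower in ILC1s at a Benjamini-Hochberg adjusted p under 0.05, and all 12 differed by at least 2-fold.

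The log2 fold changes (ILC1 minus NK, with SE) were 7.03 ± 0.63 for Gzmg, 5.71 ± 0.43 for Gzme and 3.91 ± 0.23 for Gzmc. Without ILC1 replicate 3 that of Gzmg was 6.39. Pdcd1 followed with 4.90 ± 0.40 and Sema6d, which encodes a transmembrane semaphorin, with 4.05 ± 0.33. Cxcr6 had 3.70 ± 0.34, Tmem176a, a membrane protein gene, 3.11 ± 0.29, and the fatty acid transporter family member Slc27a6 2.40 ± 0.20. Inpp4b, a phosphoinositide phosphatase gene, had 2.13 ± 0.11 with 177 ± 7.73 CPM in ILC1s and 40.5 ± 2.14 CPM in NK cells. Trgc4, a constant region of the T cell receptor gamma chain, had 2.39 ± 0.16, the oxysterol receptor gene Gpr183 1.70 ± 0.14 and Trdc -1.83 ± 0.16. Trgc4, Gpr183 and Trdc fell outside the naming rule as applied, which took only the members with the highest level from marker lists. They were named after their values were seen. The adjusted p-values of edgeR's test for the 12 genes ran from 0.0174 (Gzmc and Inpp4b) to 0.0447 (Gzmg, Cxcr6 and Tmem176a). For each of the 12 genes every ILC1 library lay on the same side of every NK library. The granzyme genes are similar in sequence and reads of 50 bases can be shared among them, so the split between Gzmc, Gzme and Gzmg is uncertain.

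**Figure D1:**
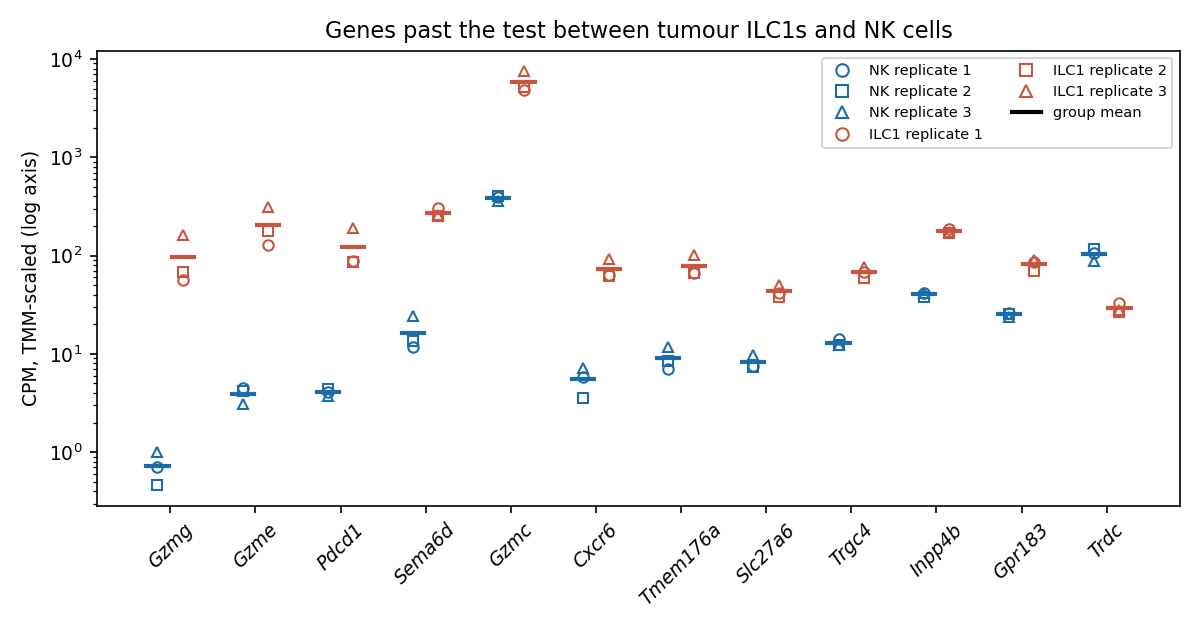
Level of the 12 genes past the test in each library, in TMM-scaled CPM on a log axis; blue symbols are NK libraries, red symbols ILC1 libraries, shapes are replicates 1 to 3 and bars are group means. The ILC1 and NK symbols do not overlap for any of the 12 genes, and Gzmc has the highest level, with a mean of 5821 CPM in ILC1s.

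These 12 calls depended on single libraries. With ILC1 replicate 1, ILC1 replicate 2, NK replicate 1 or NK replicate 2 left out, 0 genes passed edgeR's test in either direction, with 2026, 1507, 1266 and 1349 genes at an unadjusted p under 0.05. Without NK replicate 3, 250 genes were higher and 199 lower, and without ILC1 replicate 3, 11 were higher and 11 lower. DESeq2 on all 6 libraries called 396 genes higher and 412 lower, and these included all 12. It gave no adjusted p for 15 of 16 macrophage markers, 6 of 12 dendritic cell markers and at most 2 members of each other list, and these count as not called. Across every alternative run, the 12 genes kept the sign of their fold change.

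On GRCm38, Gzme (14:56117626-56120625), Gzmg (14:56156582-56159579) and Gzmc (14:56231441-56234656) are protein-coding genes in a single granzyme cluster on the reverse strand of chromosome 14. Gpr183 (121952551 to 121965195) lies on the same chromosome, as does Trdc (54142851 to 54148868), a T cell receptor constant gene. Pdcd1 lies on chromosome 1 (94038305 to 94052553), Sema6d on chromosome 2 (124089969 to 124667770), Tmem176a on chromosome 6 (48840919 to 48847071) and Inpp4b on chromosome 8 (81342556 to 82127914). Cxcr6 lies on chromosome 9 (123806475 to 123811760), as does Eomes (118478212 to 118486132). Slc27a6 lies on chromosome 18 (58556257 to 58612773). Trgc4 lies on chromosome 13 (19344558 to 19352343), as do Itga1 (114953096 to 115101964) and Itga2 (114833081 to 114932100). Apart from Trdc and Trgc4, these are annotated as protein-coding genes, and counts refer to the whole gene.

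The 8 lineage and gate genes fixed in advance did not pass edgeR's test over all genes, where 7 had an unadjusted p under 0.05, DESeq2 called 3 higher and 3 lower, and limma-voom called 1. Eomes, a transcription factor of NK cells, had 125 ± 51.8 CPM in ILC1s and 494 ± 115 CPM in NK cells (log2 fold change -1.98 ± 0.38, edgeR adjusted p = 0.127). Itga2, which encodes the NK cell integrin CD49b, had 12.3 ± 8.45 against 118 ± 27.9 CPM (-3.27 ± 0.61, edgeR adjusted p = 0.129). Itga1, which encodes the ILC1 integrin CD49a, had 152 ± 24.2 against 45.7 ± 6.71 CPM (1.73 ± 0.18, edgeR adjusted p = 0.0579). The ILC1 and NK libraries did not overlap for any of these 3 genes. Tbx21 had 220 ± 21.8 and 242 ± 52.2 CPM, and Ncr1 347 ± 15.9 and 570 ± 140 CPM, in ILC1s and NK cells. Klrb1c had 351 ± 10.96 and 900 ± 257 CPM (edgeR adjusted p = 0.120). Cd200r1 had a log2 fold change of 2.34 ± 0.57 and the IL-7 receptor gene Il7r of 1.72 ± 0.58, with edgeR adjusted p = 0.173 and 0.276, and without ILC1 replicate 3 these were 1.66 and 0.83. Without ILC1 replicate 1 the log2 fold change of Itga2 was -3.90.

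The libraries did not group by cell type alone. The Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.989 between ILC1 replicates 1 and 2, and 0.977 and 0.971 between each of these and NK replicate 3. It was 0.948 between NK replicates 1 and 2, 0.880 between each of these and NK replicate 3, and 0.878 between ILC1 replicates 1 and 3. Every pair differed by more than counting noise, with a median chi-square per gene of 2.42 or more where counting alone gives 0.455. Mitochondrial genes took 3.30, 3.07 and 2.65% of the counts in NK replicate 3 and ILC1 replicates 1 and 2, and 1.72, 1.39 and 1.93% in NK replicates 1 and 2 and ILC1 replicate 3. The unnamed gene model CT010467.1, picked out after its values were seen, was at 6188 and 6584 CPM in NK replicates 1 and 2 and at 1391 to 2525 CPM in the others. Matrix genes also followed the grouping. Col3a1, a collagen gene, was at 403 CPM in NK replicate 3 and at 472 and 762 CPM in ILC1 replicates 1 and 2, against 0.350 and 4.16 CPM in NK replicates 1 and 2 and 20.8 CPM in ILC1 replicate 3. The macrophage lysozyme gene Lyz2 was at 5838 CPM in ILC1 replicate 3, against 117 and 94.2 CPM in the other ILC1 libraries and 29.8, 32.8 and 92.6 CPM in NK replicates 1 to 3. NK replicate 3 and ILC1 replicates 1 and 2 are called the matrix-rich libraries here, a grouping made after the data were seen. A fit with these library sets as a term, in which the group effect rests on those 3 libraries, with a lone NK library assumed to vary like the others, called 16 genes higher and 17 lower. It retained 10 of the 12 genes, all but Gpr183 and Trdc, and gave log2 fold changes of 5.94 for Gzmg, 3.11 for Cxcr6 and 2.505 for Tmem176a.

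**Figure D2:**
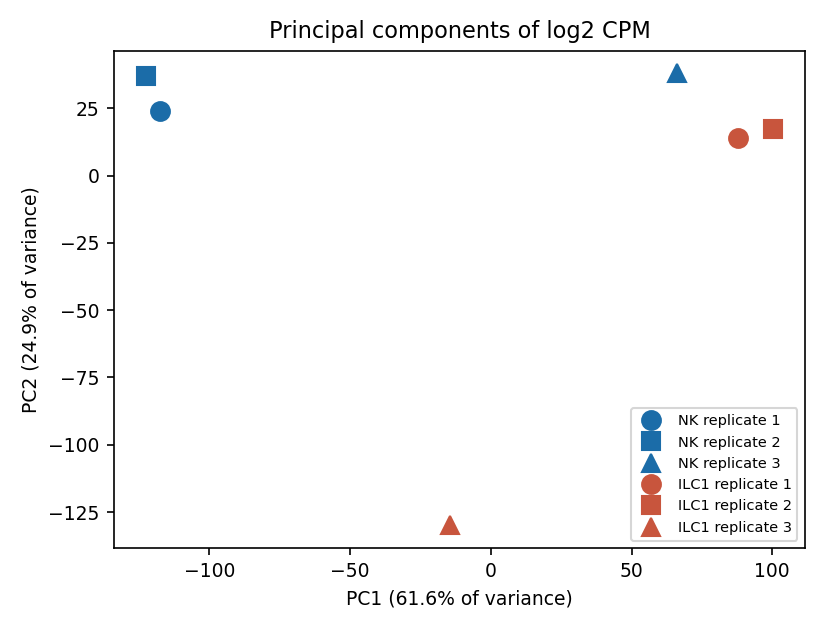
Principal components of log2 CPM over the tested genes, with PC1 (61.6% of the variance) on the x axis and PC2 (24.9%) on the y axis, in units of the component scores; each symbol is a library, blue for NK and red for ILC1. NK replicate 3 lies beside ILC1 replicates 1 and 2, and ILC1 replicate 3 stands apart on PC2.

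**Figure D3:**
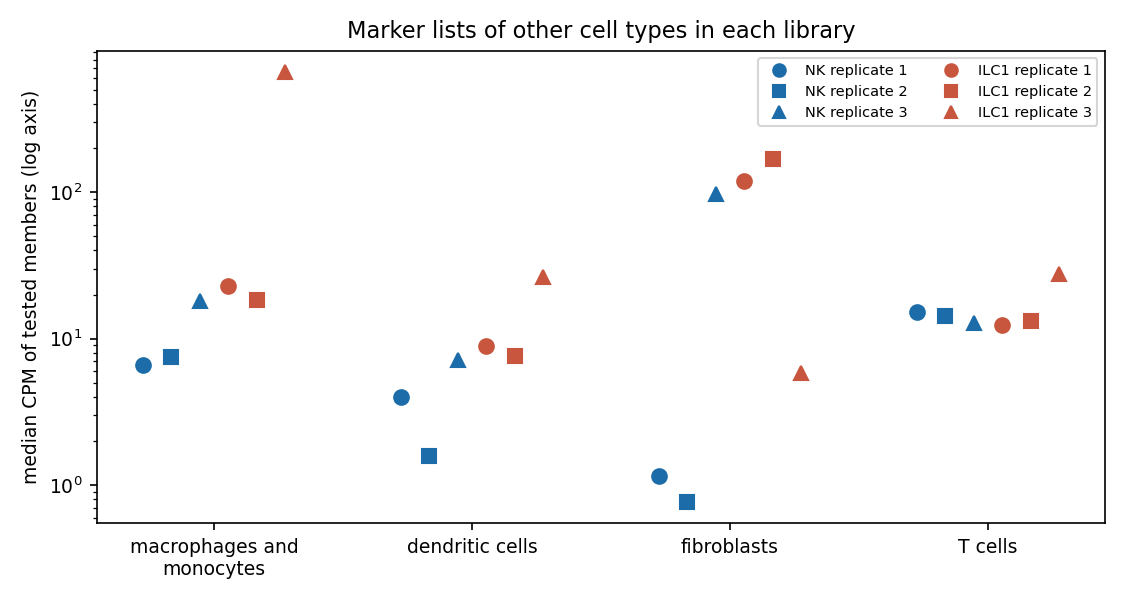
Median CPM (log axis) of the tested members of 4 marker lists in each library; colours give the cell type and shapes the replicate. The fibroblast list is at 97.2, 119 and 169 CPM in NK replicate 3 and ILC1 replicates 1 and 2, and the macrophage list at 659 CPM in ILC1 replicate 3.

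Genes typical of conventional NK cells were lower in ILC1s as a group. Of the 20 members tested, 0 passed edgeR's test over all genes (15 at an unadjusted p under 0.05, 13 lower by DESeq2, 0 by limma-voom), and 15 were lower and 0 higher when adjusted over the list alone. The median log2 fold change was -1.77, and camera, a competitive set test, placed the list below the other genes (adjusted p = 2.1e-14, and adjusted p = 0.323 with an estimated correlation). S1pr5, a receptor for exit from tissue, had -5.20 ± 0.76, the mast cell chymase gene Cma1 -4.99 ± 0.70 and the Ly49 receptor gene Klra7 -2.04 ± 0.28. With the library sets as a term these 3 fold changes were -3.61, -3.15 and -1.41. Klra genes share sequence, so reads may be split among them. Within the matrix-rich libraries 18 of the 20 members were lower in ILC1s than in NK replicate 3, with a median of -1.37.

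The list of ILC1 and residency genes was higher in ILC1s. Of its 22 members, 4 passed over all genes (Gzmc, Cxcr6, Tmem176a and Inpp4b; 14 at an unadjusted p under 0.05, 13 higher by DESeq2, 6 by limma-voom), and 14 were higher and 0 lower when adjusted over the list alone. The median log2 fold change was 1.32 (camera adjusted p = 1.3e-10, and adjusted p = 0.323 with an estimated correlation). The residency factor Hobit (Zfp683) had 51.5 ± 10.3 CPM in ILC1s and 4.97 ± 2.21 CPM in NK cells, without passing edgeR's test over all genes, and passed in 5 of 16 alternatives, DESeq2 among them. Within the matrix-rich libraries 20 of 22 members were higher in ILC1s, with a median of 1.13, and the list median without ILC1 replicate 3 was 0.81, still past camera.

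The list of tissue egress and circulation genes was lower in ILC1s, with 14 of 16 members negative. None of the 16 members passed edgeR's test over all genes (12 at an unadjusted p under 0.05, 8 lower by DESeq2, 1 by limma-voom), and 11 were lower and 0 higher when adjusted over the list alone. The median was -1.03 (camera adjusted p = 1.4e-10, and adjusted p = 0.323 with an estimated correlation). The integrin gene Itga4 had 73.8 ± 9.08 CPM in ILC1s and 240 ± 37.5 CPM in NK cells, and Samd3 75.0 ± 15.5 and 198 ± 32.3 CPM. The list of shared group 1 genes was lower as well, with a median of -0.62 over 14 members (camera adjusted p = 1.7e-07, and adjusted p = 0.516 with an estimated correlation), and of -0.29 within the matrix-rich libraries, where 3 of the 14 were higher in ILC1s. Over all genes 0 of the 14 passed edgeR's test (8 at an unadjusted p under 0.05, 6 lower by DESeq2, 0 by limma-voom), and 7 were lower and 0 higher when adjusted over the list alone. The chemokine gene Ccl5 had 89.7 ± 28.9 CPM in ILC1s and 919 ± 416 CPM in NK cells, the receptor NKG2D gene Klrk1 500 ± 55.6 and 1030 ± 181 CPM, and Cd7 119 ± 9.40 and 239 ± 56.9 CPM.

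**Figure D4:**
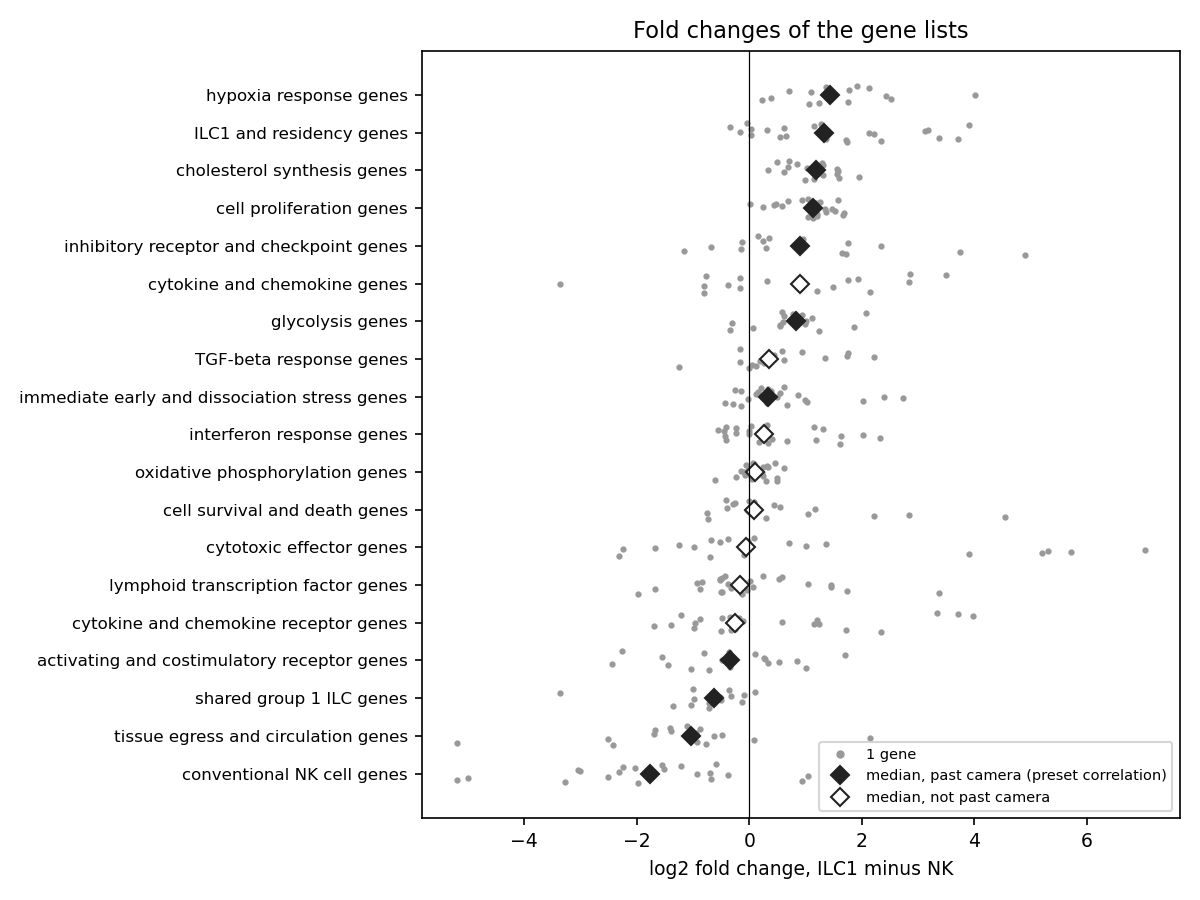
Log2 fold change (ILC1 minus NK) on the x axis of each tested member (grey points) of the 19 gene lists that are not markers of other cell types, with the list median as a diamond, filled where camera with a preset correlation passed. The conventional NK cell list has the lowest median, -1.77, and the hypoxia response list the highest, 1.43.

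Cytotoxic effector genes went both ways. Of 20 members, 3 were higher over all genes (Gzmc, Gzme and Gzmg), DESeq2 called 6 higher and 4 lower, and 6 were higher and 7 lower when adjusted over the list alone. Gzmf had 326 ± 194 CPM in ILC1s and 8.19 ± 2.09 CPM in NK cells (log2 fold change 5.31 ± 0.52, edgeR adjusted p = 0.0579, and 4.70 without ILC1 replicate 3). Granzyme B (Gzmb), named after its values were seen, had 2380.5 ± 194 and 2532 ± 450 CPM, and granzyme A (Gzma), likewise, 715 ± 339 and 3569 ± 910 CPM. The median was -0.053, the mean 0.97 and the camera direction up, without passing (adjusted p = 0.723). The list passed as higher with the library sets as a term, with a median of 0.078, and with single libraries left out the median ran from -0.22 (without ILC1 replicate 3) to 0.042 (without NK replicate 1).

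Inhibitory receptor and checkpoint genes were higher as a list, with a median of 0.91 over 17 members (camera adjusted p = 0.0115, and adjusted p = 0.575 with an estimated correlation). Pdcd1 passed over all genes, DESeq2 called 5 higher and 1 lower, and 6 members were higher and 1 lower when adjusted over the list alone. Ctla4 had 156 ± 27.3 CPM in ILC1s and 47.3 ± 4.85 CPM in NK cells, Lag3 105 ± 17.5 and 33.5 ± 10.4 CPM, and Tigit 86.4 ± 14.6 and 192 ± 38.5 CPM. The list no longer passed without ILC1 replicate 3, the library with the macrophage genes (median 0.27), or without NK replicate 3 (median 0.60), and still passed without NK replicate 2 (0.41) and with the library sets as a term (0.20). The median of 0.91 was the value of Btla, a gene at 1.93 CPM in ILC1s and 1.03 CPM in NK cells. With a minimum mean of 5 CPM the list median was 0.64, still past camera.

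Activating and costimulatory receptor genes were lower as a list, with a median of -0.35 over 18 members (camera adjusted p = 0.0386, and adjusted p = 0.575 with an estimated correlation). Over all genes 0 passed edgeR's test (9 at an unadjusted p under 0.05, 1 higher and 5 lower by DESeq2, 0 by limma-voom), and 2 were higher and 7 lower when adjusted over the list alone. The activating receptor gene Klrc2 had 36.8 ± 10.8 CPM in ILC1s and 175 ± 30.4 CPM in NK cells, Crtam 22.7 ± 4.98 and 61.7 ± 18.3 CPM, and Cd226 99.3 ± 11.1 and 49.1 ± 4.75 CPM. The list did not pass without ILC1 replicate 2 (median -0.26), NK replicate 1 (-0.34) or NK replicate 2 (-0.089), or with the library sets as a term (-0.082). It passed without ILC1 replicate 1 (-0.21), ILC1 replicate 3 (-0.60) or NK replicate 3 (-0.55).

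Cytokine and chemokine genes did not pass as a list (17 tested, median 0.90, camera adjusted p = 0.550). Over all genes 0 passed edgeR's test (6 at an unadjusted p under 0.05, 3 higher and 2 lower by DESeq2, 0 by limma-voom), and 2 were higher and 2 lower when adjusted over the list alone. Lymphotoxin alpha (Lta) had 32.4 ± 3.23 CPM in ILC1s and 8.52 ± 2.86 CPM in NK cells, Flt3l 43.6 ± 8.07 and 74.2 ± 8.87 CPM, and osteopontin (Spp1) 1099 ± 949 and 153 ± 71.3 CPM, with 2195 CPM in ILC1 replicate 3 (log2 fold change 2.85, and 1.83 without it). Without that library the list median was -0.27, without NK replicate 1 it was 0.59 and with a minimum mean of 5 CPM it was 0.30. Cytokine and chemokine receptor genes did not pass either (23 tested, camera direction down, median -0.25, mean 0.42, adjusted p = 0.498). Cxcr6 passed over all genes, DESeq2 called 5 higher and 5 lower, the median was -0.12 without ILC1 replicate 2, and 4 members were higher and 5 lower when adjusted over the list alone. The IL-2 receptor gene Il2ra had 80.2 ± 8.10 and 15.7 ± 4.62 CPM, Ccr8 14.7 ± 2.95 and 0.927 ± 0.329 CPM, and the IL-18 receptor gene Il18r1 108 ± 33.6 and 348 ± 61.2 CPM.

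Lymphoid transcription factor genes did not pass as a list (27 tested, camera direction down, median -0.16, mean 0.0044, adjusted p = 0.0588). Over all genes 0 members passed edgeR's test (9 at an unadjusted p under 0.05, 2 higher and 2 lower by DESeq2, 0 by limma-voom), and 2 were higher and 2 lower when adjusted over the list alone. Tcf7, which encodes TCF-1, had 178 ± 70.4 CPM in ILC1s and 566 ± 103 CPM in NK cells, and Rora 39.8 ± 10.0 and 11.9 ± 5.82 CPM. The list passed as lower without ILC1 replicate 1 (median -0.21) or ILC1 replicate 3 (-0.34), with no low-count filter (-0.13) and with the library sets as a term (-0.18). It did not pass without ILC1 replicate 2 (-0.087) or NK replicate 3 (-0.26). TGF-beta response genes did not pass (16 tested, median 0.35, camera adjusted p = 0.0507). Of its members 0 passed edgeR's test over all genes (5 at an unadjusted p under 0.05, 3 higher and 1 lower by DESeq2, 1 by limma-voom), and 1 was higher and 1 lower when adjusted over the list alone. The integrin gene Itgae had 10.2 ± 5.51 and 2.18 ± 1.22 CPM, and Smad3 66.0 ± 17.8 and 157 ± 23.6 CPM. This list passed as higher without ILC1 replicate 1 (median 0.41) or ILC1 replicate 2 (0.41) and with a minimum mean of 5 CPM (0.34), and did not pass without NK replicate 3 (0.55).

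Cholesterol synthesis genes were higher in ILC1s as a list. All 18 members had a positive fold change and groups that did not overlap. In edgeR's test over all genes 0 passed (17 at an unadjusted p under 0.05, 10 higher by DESeq2, 0 by limma-voom), and 17 were higher and 0 lower when adjusted over the list alone. The median was 1.19 (camera adjusted p = 5.4e-12, and adjusted p = 0.323 with an estimated correlation). The squalene synthase gene Fdft1 had 70.8 ± 10.8 CPM in ILC1s and 30.1 ± 6.38 CPM in NK cells, and Srebf2, the transcriptional regulator of the pathway, 359 ± 27.7 and 199 ± 17.4 CPM. Within the matrix-rich libraries all 18 were higher in ILC1s than in NK replicate 3, with a median of 0.68, where the fibroblast marker list had a median of 0.59.

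Hypoxia response genes were higher as a list, with 15 of 15 tested members positive and a median of 1.43 (camera adjusted p = 3.1e-07, and adjusted p = 0.575 with an estimated correlation). None passed edgeR's test over all genes or when adjusted over the list alone, with 11 at an unadjusted p under 0.05, 10 higher by DESeq2 and 0 by limma-voom. Hilpda, a lipid droplet gene, had 169 ± 123 CPM in ILC1s and 45.01 ± 3.73 CPM in NK cells, with the highest value, 311 CPM, in ILC1 replicate 3, and log2 fold changes of 1.91 and, without that library, 1.12, and the median within the matrix-rich libraries was 0.34. Glycolysis genes were also higher as a list (18 tested, median 0.83, camera adjusted p = 0.000639, and adjusted p = 0.575 with an estimated correlation). None of these passed edgeR's test over all genes or when adjusted over the list alone, with 10 at an unadjusted p under 0.05, 3 higher by DESeq2 and 0 by limma-voom. Phosphoglycerate kinase (Pgk1) had 1056 ± 403 and 489 ± 71.7 CPM, with 1513 CPM in ILC1 replicate 3. The glycolysis list median was 0.43 without that library, still past camera, and 0.44 within the matrix-rich libraries. There the fibroblast marker list had a median of 0.59, above those of the hypoxia and glycolysis lists.

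Cell proliferation genes were higher as a list, with 24 of 24 members positive and a median of 1.14 (camera adjusted p = 5.6e-05, and adjusted p = 0.575 with an estimated correlation). None passed edgeR's test over all genes or when adjusted over the list alone, with 3 at an unadjusted p under 0.05, 2 higher by DESeq2 and 0 by limma-voom. Cyclin B2 (Ccnb2) had 29.4 ± 3.86 CPM in ILC1s and 9.20 ± 7.25 CPM in NK cells, and Stmn1 105 ± 36.6 and 51.1 ± 19.9 CPM. The log2 fold change of Ccnb2 was 1.67, and 2.55 without NK replicate 3. The list median was 31.7, 52.0 and 56.3 CPM in NK replicate 3 and ILC1 replicates 1 and 2, the libraries rich in matrix genes, and 8.99, 9.53 and 18.7 CPM in NK replicates 1 and 2 and ILC1 replicate 3. All 24 members were higher in ILC1s than in NK replicate 3 within the matrix-rich libraries, with a median of 0.63. In that comparison the fibroblast and endothelial marker lists had medians of 0.59 and 1.16, so a median shift of this size was not particular to proliferation genes. The endothelial list was at low levels, with a median of 2.09 CPM in NK replicate 3. Of the 12 fibroblast markers 10 were higher in ILC1s there, and of the 12 endothelial markers 12. Without NK replicate 3 the median of the proliferation list was 2.02.

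Oxidative phosphorylation genes did not pass as a list (24 tested, median 0.11, camera adjusted p = 0.550). In edgeR's test 0 members passed over all genes or when adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Cox5a had 93.6 ± 23.9 CPM in ILC1s and 61.3 ± 11.4 CPM in NK cells. The list passed as higher without ILC1 replicate 1 (median 0.23) and with the library sets as a term (0.17). Its median was -0.089 without ILC1 replicate 3, 0.016 without NK replicate 3 and 0.19 without NK replicate 2, without passing. Interferon response genes did not pass (24 tested, median 0.26, camera adjusted p = 0.547). Here too 0 members passed edgeR's test over all genes or when adjusted over the list alone, with 6 at an unadjusted p under 0.05, 6 higher by DESeq2 and 0 by limma-voom. Isg15 had 39.5 ± 26.9 and 12.97 ± 4.76 CPM, with 70.3 CPM in ILC1 replicate 3 (log2 fold change 1.60, and 0.87 without it). With the library sets as a term the list passed as lower, with a median of -0.10. Its median was -0.072 without ILC1 replicate 3 and 0.40 without ILC1 replicate 1, without passing.

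Immediate early and dissociation stress genes were higher as a list (23 tested, median 0.34, camera adjusted p = 0.0326, and adjusted p = 0.627 with an estimated correlation). Over all genes 0 passed edgeR's test (2 at an unadjusted p under 0.05, 2 higher by DESeq2, 0 by limma-voom), and 1 was higher and 0 lower when adjusted over the list alone. Nr4a3 had 165 ± 20.1 CPM in ILC1s and 90.1 ± 2.59 CPM in NK cells, and Atf3 328 ± 213 and 62.1 ± 63.1 CPM, with log2 fold changes of 2.40, 1.69 without ILC1 replicate 3 and 3.68 without NK replicate 3. The list did not pass without ILC1 replicate 3 (median 0.29), NK replicate 1 (0.26) or NK replicate 2 (0.24), it passed without NK replicate 3 (0.73), and its direction turned with the library sets as a term (median -0.042). Cell survival and death genes did not pass (19 tested, camera direction down, median 0.089, mean 0.55, adjusted p = 0.712), and the median ran from -0.11 without ILC1 replicate 3 to 0.21 without ILC1 replicate 2. Of its members 0 passed edgeR's test over all genes (6 at an unadjusted p under 0.05, 2 higher and 2 lower by DESeq2, 0 by limma-voom), and 1 was higher and 2 lower when adjusted over the list alone. The pro-apoptotic gene Bcl2l11 had 274 ± 35.3 and 461 ± 28.1 CPM, and Bcl2 237 ± 50.9 and 396 ± 24.0 CPM. Bcl2a1d, which shares reads with its near-identical copies, had 58.1 ± 46.7 and 8.17 ± 1.48 CPM, with log2 fold changes of 2.83 and, without ILC1 replicate 3, 1.92.

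Macrophage and monocyte markers were higher in ILC1s as a list, with a median of 4.70 over 16 members (camera adjusted p = 0.000255, and adjusted p = 0.575 with an estimated correlation), and 0 members passed edgeR's test over all genes or when adjusted over the list alone (10 at an unadjusted p under 0.05, 0 by limma-voom, and 0 by DESeq2, which gave no adjusted p for 15 of them). In ILC1 replicate 3 the arginase gene Arg1 was at 4608 CPM against 77.7 and 53.0 CPM in ILC1 replicates 1 and 2. Without that library the list median was 0.96 and the list still passed. With the library sets as a term the median was 0.29 and the list did not pass. Dendritic cell markers, which include MHC class II genes, had a median of 3.56 over 12 members (camera adjusted p = 0.000499, and adjusted p = 0.516 with an estimated correlation), and 0 passed edgeR's test over all genes or over the list alone (8 at an unadjusted p under 0.05, 1 higher by DESeq2, which gave no adjusted p for 6, and 0 by limma-voom). The list still passed without ILC1 replicate 3 (median 1.39) and with the library sets as a term (1.12). Its member Cd74 was at 4483 CPM in ILC1 replicate 3, at 220 and 181 CPM in ILC1 replicates 1 and 2 and at 77.9, 53.8 and 95.1 CPM in NK replicates 1 to 3.

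Fibroblast markers had a median of 1.59 over 12 members (camera adjusted p = 0.00522, and adjusted p = 0.575 with an estimated correlation), and the list did not pass with the library sets as a term (median 0.59). Without NK replicate 3 its median was 6.56, and without ILC1 replicate 2, NK replicate 1 or NK replicate 2 it was 0.93, 0.96 or 1.01, past camera in each case. No fibroblast marker passed edgeR's test over all genes or over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Fibronectin (Fn1) was at 428, 543 and 575 CPM in the matrix-rich libraries, at 5896 CPM in ILC1 replicate 3 and at 2.997 and 6.47 CPM in NK replicates 1 and 2. Endothelial markers had a median of 2.58 over 12 members (camera adjusted p = 0.00287, and adjusted p = 0.575 with an estimated correlation), from low levels such as 12.2 ± 6.74 CPM in ILC1s and 1.50 ± 2.33 CPM in NK cells for Eng (log2 fold change 3.02, and from 2.42 without ILC1 replicate 3 or NK replicate 1 to 6.26 without NK replicate 3). The median level of the list was 0, 0 and 2.09 CPM in NK replicates 1 to 3. In ILC1 replicates 1 to 3 it was 4.87, 3.90 and 0.493 CPM. The median log2 fold change was 7.43 without NK replicate 3 and 1.21 with the library sets as a term, past camera in both. No endothelial marker passed edgeR's test over all genes or over the list alone, with 1 at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 by limma-voom. T cell markers did not pass (15 tested, median 0.43, camera adjusted p = 0.963), and their median was 0.060 without ILC1 replicate 3, 0.70 without ILC1 replicate 1 and -0.082 with a minimum mean of 5 CPM. Of these Trdc was lower over all genes, DESeq2 called 2 higher and 2 lower, 0 were higher and 2 lower when adjusted over the list alone, and Trbc2 had 118 ± 16 and 107 ± 7.16 CPM.

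The remaining marker lists did not pass camera. Their adjusted p-values were 0.802 for B and plasma cells (8 tested), 0.592 for neutrophils (8 tested), 0.622 for tumour epithelium (9 tested), 0.550 for ILC2s and ILC3s (5 tested) and 0.157 for erythroid, platelet, mast and basophil cells (8 tested). In these 5 lists 0 members passed edgeR's test over all genes or limma-voom. At an unadjusted p under 0.05 there were 0, 1, 2, 2 and 0 members in the same order, and DESeq2 called 0, 1 (lower), 1 (higher), 1 (higher) and 3 (lower). Cdh1 in the epithelial list and Nrp1 in the ILC2 and ILC3 list, the latter named after its value was seen, were higher when adjusted over the list alone. For the erythroid, platelet, mast and basophil list camera passed as higher with the library sets as a term (median 1.40). Cdh1, which encodes E-cadherin, had 194 ± 159 CPM in ILC1s and 16.6 ± 5.87 CPM in NK cells, with 377 CPM in ILC1 replicate 3, and log2 fold changes of 3.54 and, without that library, 2.62. The neutrophil marker Mmp9 was at 451 and 133 CPM in NK replicates 1 and 2 and between 7.96 and 8.82 CPM in the other libraries. It made up most of its list there, with list sums of 463 and 139 CPM. Csf3r, another member, was at 0.350 and 0.565 CPM in NK replicates 1 and 2, 9.66 CPM in NK replicate 3 and 4.92 to 44.9 CPM in ILC1s. Of the 8 neutrophil markers tested, 5 had a positive and 3 a negative fold change. In all, 15 of the 29 lists passed camera with a preset correlation, 11 higher and 4 lower, and 0 passed with an estimated correlation.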

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

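The term for library sets, the library weights and the fit to NK replicate 3 with ILC1 replicates 1 and 2 alone were chosen after seeing the data. The counts of 11 genes higher and 1 lower, equal to the counts at 2-fold or more, changed by less than 1.5 times with RLE (12 and 1) and upper-quartile normalization (13 and 1). With no low-count filter 47 genes were higher and 91 lower, 47 and 90 of them by at least 2-fold, where 26185 genes were tested, and the share of higher calls was 34.1% against 91.7%. With a minimum mean of 5 CPM, 2 genes were lower, each by at least 2-fold. With single libraries left out, the counts ran from 0 to 250 higher and 0 to 199 lower, and from 0 to 242 and 0 to 162 by at least 2-fold. The highest of these came without NK replicate 3, and counts of 0 came without ILC1 replicate 1 or 2 or NK replicate 1 or 2. Limma-voom called 16 genes higher and 2 lower, both of the latter by 2-fold or more. DESeq2 called 396 and 412, of which 350 and 269 by at least 2-fold. With library weights, where NK replicate 3 and ILC1 replicate 3 weigh least, limma-voom called 1127 and 1085, of which 810 and 392 by at least 2-fold. With the library sets as a term 16 genes were higher and 17 lower, all by at least 2-fold. In NK replicate 3, ILC1 replicate 1 and ILC1 replicate 2 alone, 956 were higher and 935 lower, of which 361 and 319 by at least 2-fold. That fit has a lone NK library, assumed to vary like the ILC1 libraries, and 1 residual degree of freedom. Beyond the number of genes or libraries that a setting itself changes, the cause of these differences was not tested.

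The 12 genes kept their sign under every alternative run. All 12 stayed past the threshold with both other normalizations, both other filters, without NK replicate 3, with DESeq2 and with library weights, and 10 did so without ILC1 replicate 3, with limma-voom and with the library sets as a term, where NK replicate 3 stands alone against ILC1 replicates 1 and 2. Over the 135 genes named by the rule or chosen later and all alternatives, 1730 values stayed on the same side of the threshold with the same direction, 339 newly passed, 66 no longer passed and 23 uncalled values changed sign. No scaling moved the median of all genes by more than 0.1 on the log2 scale.

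The replicate number as a block left 0 genes higher and 0 lower, and 0 and 0 by at least 2-fold, in edgeR's test, with 1584 genes at an unadjusted p under 0.05, and 17 lists passed camera, with the transcription factor and TGF-beta response lists among them. Samples with the same number did not deviate together (r = -0.363, -0.355 and -0.564 across genes for replicates 1, 2 and 3), and no sample correlated best with its own number. Deviations from a mean of 3 libraries depend on each other, and NK replicate 3 and ILC1 replicate 3 stood apart within their groups. These values therefore cannot exclude a shared mouse or day. The numbers are treated as names because no label ties them to one.

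The 15 lists past camera became 15, 15, 16 and 15 with the other normalizations and filters (24 lists had enough members under the minimum of 5 CPM), 13 to 18 with single libraries left out, 16 with the library sets as a term (11 of the 15 among them), and 0 with an estimated correlation. With the library sets as a term, the median of the interferon response list was -0.103, past camera as lower, and that of the immediate early and dissociation stress list was -0.0416, not past it. The cause was not tested. The mean correlation within cell types exceeded that between them by 0.0266, by 0.0282 with a prior count of 0.5, and by -0.0832 over the 500 most variable genes. Depth was near equal among libraries, and the spread between them limits the test more than counting does: in simulated data with the real spread 29 of 50 genes changed 4-fold were recovered, and 50 of 50 with the dispersion capped at 0.05.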

Other observations

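The genes of the first 2 paragraphs were chosen after their values were seen, and so were the tests on macrophage genes, matrix genes and Eomes, while the counts over other splits of the samples were planned before. Several further genes differed between ILC1s and NK cells in every library without passing edgeR's test over all genes, and DESeq2 called each of the 5 given here. Ifitm1 and Ifitm2, interferon-induced transmembrane protein genes, had 231 ± 111 and 116 ± 66.0 CPM in ILC1s and 14.1 ± 5.81 and 8.52 ± 3.76 CPM in NK cells. The log2 fold change of Ifitm2 was 3.77, and 3.18 without ILC1 replicate 3. The TNF family ligand genes Tnfsf11 (RANKL) and Tnfsf4 (OX40L) had 32.5 ± 4.64 and 19.2 ± 1.57 CPM in ILC1s and 8.36 ± 4.17 and 5.14 ± 1.58 CPM in NK cells. The transcription factor gene Arnt2 had 20.7 ± 4.70 against 0.751 ± 0.523 CPM. Their log2 fold changes in NK replicate 3 against ILC1 replicates 1 and 2 alone were 3.57, 2.64, 2.54, 2.56 and 3.75, in the same order.

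Further genes were lower in ILC1s. Klra4 and Klra8 had 69.9 ± 44.7 and 60.2 ± 38.04 CPM in ILC1s and 574 ± 163 and 482 ± 94.0 CPM in NK cells, Klri2 117 ± 27.3 against 508 ± 117 CPM, and Klrc3 5.33 ± 1.40 against 23.0 ± 3.56 CPM. Myb, a transcription factor gene, had 18.2 ± 10.97 against 80.8 ± 4.70 CPM, the sphingosine phosphate receptor gene S1pr1 6.69 ± 3.48 against 35.8 ± 6.55 CPM and the chemokine receptor gene Cxcr4 210 ± 87.2 against 547 ± 20.2 CPM. None of these 7 passed edgeR's test over all genes, and DESeq2 called all 7. Of all genes with at least 10 CPM in the higher group, groups that did not overlap and a difference of at least 2-fold in the same direction between NK replicate 3 and ILC1 replicates 1 and 2, 136 were higher in ILC1s and 100 lower. Among the 14475 genes tested, the groups did not overlap for 3741. The same libraries enter both conditions, and no chance level was computed for these counts.

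The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. As many genes as the 11 higher came from 2 of the 10 splits, the real one included, with 1002 as the highest other count. For the 1 gene lower the number was 2 of 10 and the highest other 203, for the 11 higher by at least 2-fold 2 of 10 and 906, and for the 1 lower by at least 2-fold 2 of 10 and 35. For the 15 lists it was 4 of 10, with 17 as the highest and 6 as the lowest other. The split with the high gene counts sets NK replicate 3 and ILC1 replicates 1 and 2 against the rest and called 1205 genes, which points to a structure of the samples other than cell type. Within those 3 libraries 956 genes were higher and 935 lower in ILC1s, with 1 residual degree of freedom.

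ILC1 replicate 3 stood out by macrophage and antigen presentation genes, such as Lyz2 (5838 CPM), Arg1 (4608), Cd74 (4483) and Cd14 (2562). A wrong label was argued against by 97.4% (38 of 39) of the genes at 10 CPM or more and at least 4-fold higher in ILC1 replicates 1 and 2 than in NK replicate 3, which lay above every NK library in ILC1 replicate 3 too. RNA or cells of macrophages or monocytes may account for the pattern, but no test set this apart, since the 16 markers, a median of 29.2-fold above the other ILC1 libraries, are part of the pattern itself. None of the 16 is in another list, and 7 were at 10 CPM or more in NK replicates 1 and 2. A sort for innate lymphoid cells is meant to remove such cells, but its markers are not given, so how many it removed is not known. No biological explanation was tested, and a different state of the ILC1s in that sample stays open.

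Matrix genes were high in NK replicate 3 and ILC1 replicates 1 and 2, across the cell types, and 10 of 12 fibroblast markers were below 10% of that level in NK replicates 1 and 2. Loss of transcripts through lower library complexity in NK replicates 1 and 2 was argued against, since 3.03% (55 of 1817) of genes at 100 to 1000 CPM were lost in that way. RNA of fibroblasts or of mesenchymal tumour cells may be present in the 3 libraries: the log2 ratio to NK replicate 3 over the 12 markers had an SD of 0.287 in ILC1 replicate 1 and 0.532 in ILC1 replicate 2, and 32.9% and 75.5% of 1000 random gene sets had as low an SD, which leaves a shared source open. Col3a1 was at 403, 472 and 762 CPM in the 3 libraries, and none of the 12 is in another list. Fn1 was at 428, 543 and 575 CPM there but at 5896 CPM in ILC1 replicate 3, so it was not particular to the 3 libraries. Thy1 (527, 797 and 851 CPM in the 3 libraries, 694 and 761 CPM in NK replicates 1 and 2) did not follow the pattern. Which cells gave this RNA was not tested. A sort for lymphoid cells is meant to remove them, but its markers are not given, so how many it removed is not known. A difference in preparation stays open, since the mitochondrial share followed the same grouping (2.65 to 3.30% against 1.39 to 1.93%). No biological explanation was tested because the pattern does not follow cell type.

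Eomes, lower in ILC1s, was still at 170 and 137 CPM in ILC1 replicates 1 and 2, against 361 CPM in NK replicate 3. NK cells in the ILC1 gate as the whole source would put their other genes at the share of Eomes or above. The median ratio to NK replicate 3 was 0.192 over 6 other genes (Ccl5, Itga2, S1pr5, Cma1, Klra4 and Klra8), picked after their values were seen. For Eomes it was 0.424, with a spread of 0.0657 between the 2 ILC1 libraries. Over the 20 conventional NK genes fixed in advance, Eomes among them, the median log2 difference from NK replicate 3 was -1.37. That of Eomes was -1.24. A list median cannot decide, since genes that ILC1s also express can lie above the share of Eomes. Genes below that share are what the explanation forbids, and the 6 genes ran from 0.0821 (S1pr5) to 0.238 (Klra4). Their values argue against NK cells like those of NK replicate 3 as the whole source, for these genes and with NK replicate 3 alone as the reference. ILC1 RNA in NK replicate 3 that narrowed the gap was argued against, since Eomes there lay at 0.489 of the way from NK replicates 1 and 2 to ILC1 replicates 1 and 2, but the 10 members of the ILC1 and residency list at 10 CPM or more and at least 2-fold higher in those ILC1 than in those NK libraries lay at a median of 0.0293 (SD 0.143, highest 0.434 for Il7r). Some Eomes expression by cells of the ILC1 gate, or NK cells of another state within it, may remain as hypotheses, and neither was tested. NK cells like those of NK replicate 3 in the ILC1 gate stay open as a part of the source.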
